A study of Mus musculus with 12 samples.

How the data were processed

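Tregs were sorted by the authors from spleen and lymph nodes of female C57BL/6 mice with a Foxp3-linked YFP-Cre and 1 (HET) or 2 (KO) floxed Ezh2 alleles, as CD62Lhi and CD62Llo cells, per the labels' protocols. Poly(A) libraries were read as single ends of 50 bp on an Illumina HiSeq. Per the submitters' processing notes the authors made the FPKM values with CASAVA 1.8.2, FastQC, TopHat and Cufflinks 2.1.1 on mm10, and the settings and the TopHat version are not given in the sources used here. The lower and upper interval bounds of each FPKM were deposited by the authors beside it, and these 2 other values were used here for the implied depth and for 1 alternative.

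Each of the 12 deposited files held the same 23846 gene entries with 23352 symbols, and the entries of the 250 symbols with more than 1 were summed. Of 23102 symbols with 1 entry, 21242 were found on the same chromosome of the mm10 reference annotation and 21196 overlapped its locus, which checked the build. Entries marked as having too little data numbered 311 in each file, 5 to 184 of them with an FPKM above 0, and were kept with the FPKM given, so 60 tested symbols hold such an entry. Read counts were not used here, so no count model was fitted. The implied depth of each library is given in the report, was computed from the interval taken as 2 SD to each side, and is an estimate. In each of the 11 libraries 12.1% to 30.8% of the entries with an FPKM above 1 had an FPKM above their own upper bound, for a reason not given in the sources used here, so the depths are uncertain. No other rescaling was applied to the FPKM.

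HET CD62Lhi replicate 3 was left out because its label says the submitters did so for low read counts. The other 11 libraries were fitted together in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1) with 4 group means, empirical Bayes with a trend, and Benjamini-Hochberg adjustment at 0.05, for genes with an FPKM of at least 1 in at least 2 libraries. The contrasts were CD62Llo against CD62Lhi in HET and in KO, KO against HET in CD62Lhi and in CD62Llo, and the interaction. These choices, the gene lists and most of the alternatives below were made before the data were examined.

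The 25 gene lists were tested with limma camera at a preset correlation of 0.01, and again with an estimated correlation (statmod 1.5.0), with Benjamini-Hochberg over the lists of a contrast. They cover Treg identity, activated Tregs, resting T cells, PRC2, PRC1, classical Polycomb targets, helper lineages, co-inhibitory and trafficking receptors, cell cycle, interferon-stimulated, immediate early and stress, apoptosis and p53, glycolysis, cholesterol synthesis and TGF-beta and Smad genes. Further lists cover ribosomal protein, mitochondrially encoded and histone genes and markers of B cells, plasma cells, CD8 T and NK cells, myeloid cells, red cells and platelets, and stroma and endothelium. Lists with fewer than 3 tested members were given values and no test. Some genes stand in several lists, such as Tigit and Gzmb.

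Genes were named by a fixed rule. Per contrast it took the 10 most raised and 10 most lowered called genes with separated groups and a mean FPKM of at least 5 in the higher group, leaving out predicted, small RNA, receptor segment and pseudogene symbols. It added up to 4 called members of each list, or 2 if none was called, and always a fixed set that includes Ezh2, Foxp3, Cd44, Il2ra, Ctla4 and Ifng. Some genes that the rule picks are not reported here. Mir1905 and Mex3a, genes outside the HET range by at least 1.2-fold with a highest group mean of at least 3, and members of lists shown for contrasts in which the rule did not pick them were named after their values were seen.

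The fit and the list test were tested on simulated data with 200 changed genes among 11431 in 5 simulations per contrast. The changed genes were taken from those with a mean log2(FPKM + 1) above 1. At log2 changes of 0.5, 1 and 2 the share recovered was 64.2%, 94.9% and 96.1% between HET fractions with 6 false calls per simulation, and 74.0%, 92.5% and 97.0% between KO fractions with 7.8. It was 64.8%, 90.7% and 98.2% for KO against HET in CD62Lhi with 9 false calls, 74.0%, 94.9% and 99.1% in CD62Llo with 4.2, and 38.2%, 88.4% and 97.0% for the interaction with 4.8. A list shifted by 0.5 was found in 5 of 5 simulations of each contrast. Over the 5 simulations, with 18 other lists in each, 1 call was made in KO against HET CD62Lhi and 0 in the other contrasts. Noise was drawn independently for each gene, so these simulations cannot check the preset correlation of the list test.

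The labels give groups the same replicate numbers and name no shared litter or day. Deviations from the group mean of same-numbered KO and HET CD62Llo libraries correlated at r of 0.165, 0.153 and 0.148, each best with its own number, so the numbers pair these libraries by correlation alone. Between the HET fractions the 2 remaining pairs were also each best with their own number, at r of 0.135 and 0.0732. Between the KO fractions and in CD62Lhi replicate 2 was not. Alternatives were a pseudocount of 0.1, no filter, quantile normalization, median centring, HET CD62Lhi replicate 3 included, the compared libraries alone, the replicate number as a block, array weights, a minimum absolute log2 change of 1, and each library left out in turn. The interval midpoint in place of the FPKM and the leave-one-out runs of the correlation between contrasts were added after the data were seen. Contrasts that share a group were not to be correlated with each other by the choices made at the start. The overlap and covariance of KO against HET CD62Llo with the HET fraction change, and their simulation with shared libraries, depart from that and were added after the data were seen.

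The authors' merged table holds 1 FPKM per group and no replicates, so no test could be made on it. Of the called genes found in it, 3082 of 3097 between HET fractions, 1805 of 1814 between KO fractions and 515 of 518 between KO and HET CD62Llo had the same sign there. The table summarizes the same groups, so equal signs are no independent support. Over the 11152 tested genes found, the median log2 change between HET fractions was -0.0172 there and 0.0682 here. Between KO fractions it was -0.0132 there and 0.0502 here. Protein levels and Polycomb histone marks were not analysed here.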

Results

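Regulatory T cells (Tregs) carrying 1 floxed Ezh2 allele (HET) or 2 (KO) were each parted by surface CD62L into a CD62Lhi and a CD62Llo fraction and sequenced as 3 libraries per group. The third HET CD62Lhi library, which its label sets aside for low read counts, had 589 of 23846 gene entries above 0 and was left out, so HET CD62Lhi had 2 libraries and the other 3 groups had 3 each. In units of 1e6 fragments, the FPKM and their interval bounds implied a depth of 11.9 and 9.53 for the HET CD62Lhi libraries and 12.5, 13.4 and 14.8 for HET CD62Llo. The depths were 25.1, 23.5 and 11 for KO CD62Lhi and 6.27, 10.4 and 19.3 for KO CD62Llo. Between 10597 and 11024 genes reached an FPKM of 1 in each of the 11 libraries, and 11431 genes were tested. Pearson r of log2(FPKM + 1) was 0.949 to 0.978 within groups and 0.925 to 0.966 between them. KO CD62Llo replicate 3 had r of 0.949 and 0.950 with its own group and 0.963, 0.955 and 0.960 with the KO CD62Lhi libraries. The labels do not say that the libraries of a group came from separate animals, so each p below may measure technical spread. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

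Ezh2 (mm10 chromosome 6, 47530274 to 47595030), the gene of the PRC2 methyltransferase and the target of the floxed allele, had FPKM of 12.7 and 12.5 in the HET CD62Lhi libraries and 18.2, 17.8 and 20.5 in HET CD62Llo. Its FPKM were 9.15, 11.5 and 11 in KO CD62Lhi and 12.5, 16.8 and 14.4 in KO CD62Llo. The group means were 12.6 ± 0.144 (n = 2), 18.8 ± 1.48 (n = 3), 10.6 ± 1.24 (n = 3) and 14.6 ± 2.16 (n = 3). KO minus HET gave a log2 change of -0.24 in CD62Lhi (SE 0.12, adjusted p = 1) and -0.36 in CD62Llo (SE 0.11, adjusted p = 0.113), neither past the threshold of 0.05 (limma, Benjamini-Hochberg). Without KO CD62Llo replicate 2 the CD62Llo value was -0.46 with adjusted p = 0.0437 (range over the alternatives 0.0437 to 1). The part of the gene that the floxed allele loses cannot be told apart in a whole-gene FPKM, so these values check the genotype only in part. Foxp3, the transcription factor that defines Tregs and drives the Cre, had means of 91.8 ± 2.74, 88.0 ± 6.57, 87.8 ± 3.58 and 84.2 ± 11 in the same group order and passed in no comparison. Il2ra, the high-affinity IL-2 receptor chain, had means of 123 ± 10.7, 123 ± 14.0, 121 ± 11.5 and 124 ± 14.0.

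**Figure D1:**
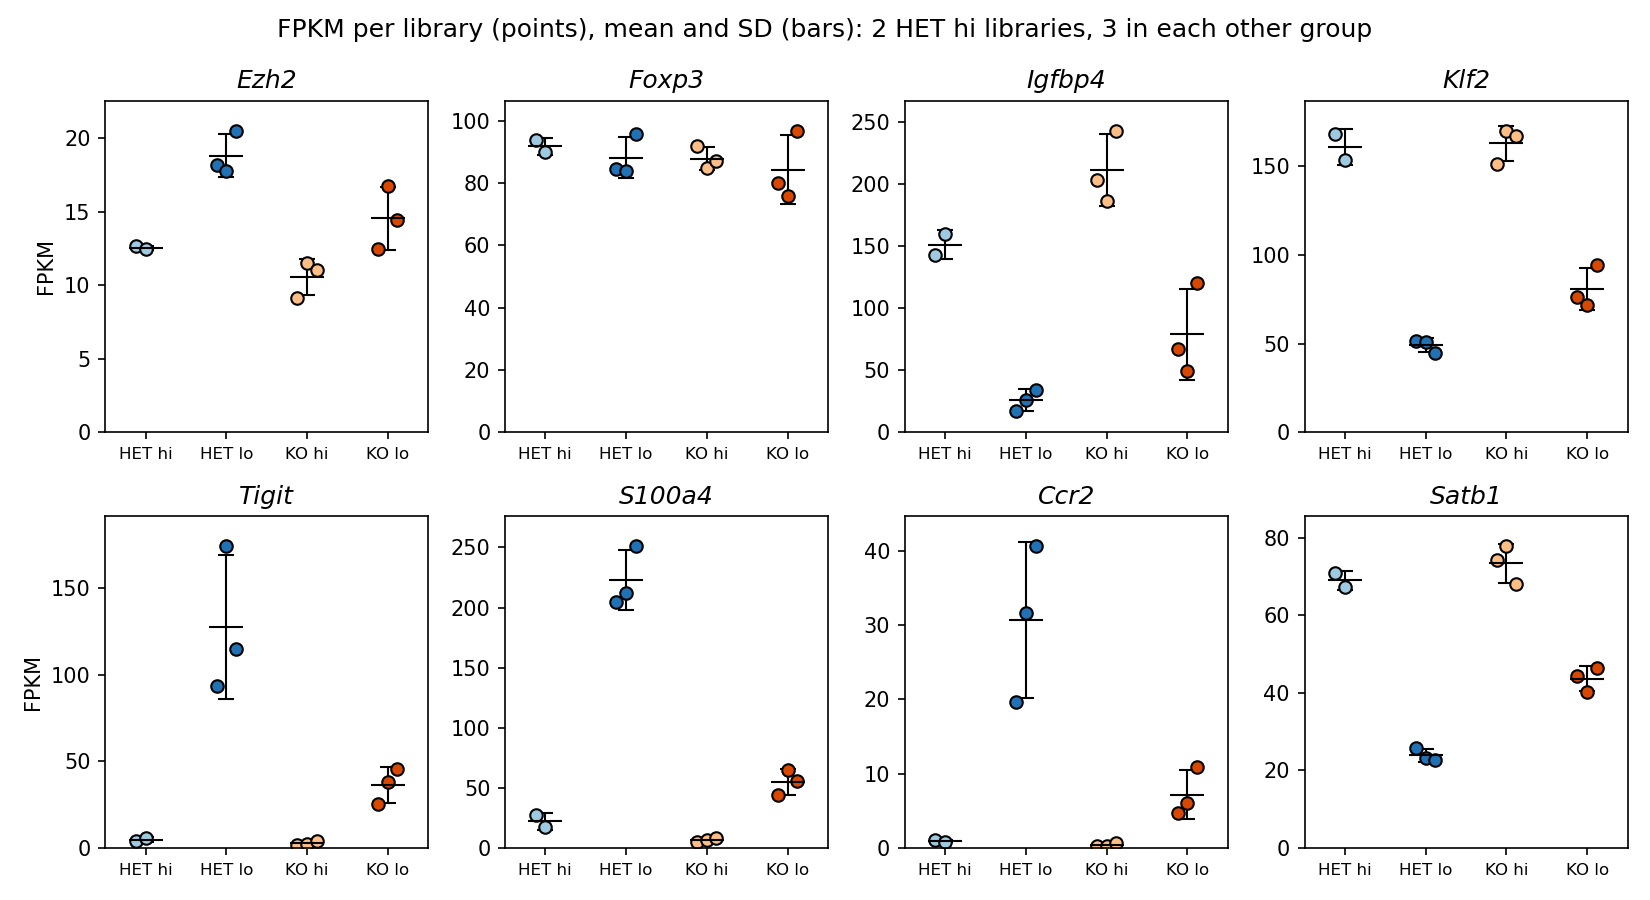
FPKM of Ezh2, Foxp3, Igfbp4, Klf2, Tigit, S100a4, Ccr2 and Satb1 in each library (points), with group mean and SD (bars) for HET CD62Lhi (n = 2), HET CD62Llo, KO CD62Lhi and KO CD62Llo (n = 3 each). Tigit averaged 128 in HET CD62Llo and 36.3 in KO CD62Llo, and Satb1 23.9 and 43.7.

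Among HET cells the CD62Llo fraction carried genes of activated, tissue-seeking Tregs at higher levels and genes of resting T cells at lower levels. Tigit (chromosome 16, 43648861 to 43664184), an inhibitory receptor, rose from 4.80 ± 1.27 (n = 2) to 128 ± 41.8 (n = 3), a log2 change of 4.44 (SE 0.35, adjusted p = 3.1e-05, limma, Benjamini-Hochberg). Ccr2, a chemokine receptor for inflamed tissue, rose from 0.911 ± 0.142 to 30.7 ± 10.5 (log2 3.99, SE 0.33), and Gzmb (chromosome 14, 56258858 to 56262260), a cytotoxic protease, rose from 1.06 ± 0.164 to 32.2 ± 9.58 (log2 3.98, SE 0.23). Lag3, another inhibitory receptor, rose from 7.19 ± 1.06 to 126 ± 30.6 (log2 3.93, SE 0.27). The transcription factor genes Maf (6.15 ± 0.167 to 85.4 ± 6.47) and Tox2 (0.802 ± 0.158 to 21.9 ± 4.59) rose as well. So did Il1r2, the decoy IL-1 receptor (2.31 ± 0.0773 to 38.0 ± 9.44). Of the 27 tested activated Treg genes, 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median log2 change of 2.56. Limma camera with Benjamini-Hochberg over the lists gave adjusted p = 9.8e-18 (adjusted p = 0.0583 with an estimated correlation). Of 29 Treg identity genes 21 rose and 0 fell (22 and 1 adjusted over the list alone, median 0.83, adjusted p = 1.2e-07, adjusted p = 0.147 with an estimated correlation). Those rises included Itgae, an integrin that binds epithelium (6.30 ± 1.73 to 53.6 ± 8.05), and Il10, an anti-inflammatory cytokine (0.410 ± 0.528 to 14.0 ± 8.04). They also included Ctla4, a co-inhibitory receptor (71.5 ± 10.8 to 217 ± 47.0, log2 1.57).

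Resting T cell genes moved the other way between the HET fractions. Of 24 tested, 19 fell and 1 rose (20 and 1 adjusted over the list alone). The median log2 change was -0.96 (limma camera, Benjamini-Hochberg adjusted p = 1.0e-14, and adjusted p = 0.0278 with an estimated correlation). Igfbp4 (chromosome 11, 99041260 to 99052643), a binding protein of insulin-like growth factors, fell from 151 ± 11.4 to 26.1 ± 8.51 (log2 -2.54, SE 0.35, adjusted p = 6.5e-04). Dapl1, a marker of naive cells, fell from 34.8 ± 1.18 to 6.63 ± 0.658 (log2 -2.24), and Klf2, the factor that keeps T cells in the circulation, had means of 161 ± 10.3 and 49.2 ± 3.72. Ly6c1 and Ly6c2, near-identical surface antigens whose reads are hard to part, fell from 137 ± 11.6 to 38.6 ± 5.41 and from 40.2 ± 5.08 to 7.10 ± 1.31. Cd44, an adhesion receptor of activated cells, rose from 11.6 ± 0.742 to 33.2 ± 2.11 (log2 1.44).

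Helper-lineage genes rose in HET CD62Llo, 18 of 23 tested with 0 falling (median log2 1.28, limma camera, Benjamini-Hochberg adjusted p = 2.6e-09, adjusted p = 0.0731 with an estimated correlation). Cxcr5, the follicle-homing receptor, rose from 10.2 ± 1.88 to 51.7 ± 11.8, and Ifng, the Th1 cytokine, from 0.396 ± 0.130 to 3.79 ± 0.294. Co-inhibitory receptor genes rose in 9 of 11 cases (median 1.25, adjusted p = 2.5e-06, adjusted p = 0.0625 with an estimated correlation). Pdcd1, which encodes PD-1, rose from 15.8 ± 3.99 to 88.6 ± 31.8 and Havcr2, which encodes Tim-3, from 0.218 ± 0.0289 to 3.76 ± 0.997. Of 30 trafficking receptor genes 19 rose and 8 fell (median 0.86, adjusted p = 0.00233, adjusted p = 0.059 with an estimated correlation). Ccr4, a skin-homing receptor, rose from 4.57 ± 0.83 to 42.8 ± 9.55, and Cxcr3, a receptor for interferon-induced chemokines, rose from 4.86 ± 1.71 to 44.9 ± 7.96. Interferon-stimulated genes fell in 14 of 28 cases and rose in 2 (median -0.29, adjusted p = 6.7e-06, adjusted p = 0.189 with an estimated correlation). Oas2, an antiviral RNA sensor, fell from 8.02 ± 0.922 to 2.40 ± 0.735 and Usp18, a brake on interferon signalling, from 38.7 ± 0.656 to 20.9 ± 2.15.

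Of 11 PRC2 genes 5 rose and 0 fell between the HET fractions (median log2 0.21, limma camera, Benjamini-Hochberg adjusted p = 0.0321, adjusted p = 0.255 with an estimated correlation). That p was 0.0692 without HET CD62Lhi replicate 1 and 0.051 without HET CD62Llo replicate 1 (range over the alternatives 0.00631 to 0.546). Aebp2, a DNA-binding PRC2 cofactor, rose from 56.7 ± 0.275 to 98.6 ± 6.35 (log2 0.78). Ezh2 rose by 0.55 (SE 0.12, adjusted p = 0.00928, but 0.0522 without HET CD62Lhi replicate 1 and 0.0578 without replicate 2, range over the alternatives 0.00515 to 0.28). Of 18 PRC1 genes 5 rose and 0 fell (adjusted p = 0.867). Pcgf2, a ring-finger subunit, rose from 0.406 ± 0.172 to 2.86 ± 0.377 and Cbx6, a chromodomain subunit, from 14.4 ± 1.54 to 27.9 ± 2.26. Of 49 classical Polycomb target genes 5 could be tested (adjusted p = 0.155).

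Ribosomal protein genes fell in 70 of 82 cases and rose in 1 in HET CD62Llo (median log2 -0.41, limma camera, Benjamini-Hochberg adjusted p = 1.1e-32, adjusted p = 0.0891 with an estimated correlation), but 8 fell after quantile normalization (median -0.04, adjusted p = 0.188) and 73 after median centring (median -0.51, adjusted p = 4.8e-28), with a range over the alternatives of 1.9e-36 to 0.188. The copies of these genes are near identical, which makes single values uncertain. Rps19, a small-subunit protein gene, had means of 2941 ± 105 and 1780 ± 237. Replication-dependent histone genes had a median of -0.19 with 1 of 47 falling (adjusted p = 0.00154, adjusted p = 0.531 with an estimated correlation). Cell cycle genes rose in 3 of 33 cases (adjusted p = 0.42). Mcm6, a helicase subunit of DNA replication, rose from 35.4 ± 1.16 to 62.6 ± 5.64.

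Immediate early and stress genes rose in 8 of 25 cases and fell in 1 in HET CD62Llo (limma camera, Benjamini-Hochberg adjusted p = 0.171). Dusp1, a phosphatase that dampens MAP kinases, rose from 10 ± 0.19 to 25.1 ± 3.63. Apoptosis and p53 genes rose in 9 of 24 cases and fell in 2 (adjusted p = 0.208). Gadd45b, a stress sensor, rose from 9.42 ± 1.28 to 28.2 ± 2.15, while Bcl2, a survival factor, fell from 69.4 ± 1.2 to 36.5 ± 0.990. Glycolysis genes rose in 11 of 19 cases and fell in 1 (adjusted p = 0.0609). Tpi1, a glycolytic isomerase, rose from 32.3 ± 1.40 to 63.8 ± 3.53. Cholesterol synthesis genes rose in 1 and fell in 2 of 20 cases (adjusted p = 0.114). TGF-beta and Smad genes rose in 4 and fell in 5 of 16 cases (adjusted p = 0.177), with a median of -0.09 but a mean of 0.07. Itgb8, which frees TGF-beta, rose from 1.55 ± 0.241 to 7.01 ± 2.20, and Smad7, an inhibitor of that signal, fell from 32.4 ± 1.15 to 15.6 ± 1.46.

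Across all genes limma with Benjamini-Hochberg called 3163 of 11431 between the HET fractions, 2148 higher and 1015 lower in CD62Llo, of which 436 and 122 had an absolute log2 change of at least 1. Higher genes made up 67.9% of the calls, whereas quantile normalization gave 1431 higher and 1638 lower and median centring 1522 higher and 1862 lower. The median of all genes shifted by -0.101 under quantile normalization and by -0.102 under median centring. The values of the 2 groups did not overlap for 6165 genes (53.9%, against 20% by chance). Leaving out HET CD62Lhi replicate 1 or replicate 2 lowered the calls to 1916 or 2012.

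Activated Treg genes also rose between the KO fractions. Tigit rose from 2.59 ± 1.29 (n = 3) in KO CD62Lhi to 36.3 ± 10.3 (n = 3) in KO CD62Llo, a log2 change of 3.40 (SE 0.31, limma, Benjamini-Hochberg adjusted p = 1.6e-04). Gzmb rose from 0.973 ± 0.266 to 17.4 ± 3.65 (log2 3.21) and Lag3 from 6.93 ± 2.19 to 67.3 ± 14.0 (log2 3.12). Maf rose from 6.05 ± 2.39 to 50.3 ± 7.28 (log2 2.90) and S100a4, a calcium-binding protein of motile cells, from 6.72 ± 1.70 to 54.9 ± 10.6 (log2 2.86). Ebi3, a subunit of IL-35, rose from 2.03 ± 0.426 to 10.5 ± 1.28. Of 27 activated Treg genes 22 rose and 0 fell (25 and 0 adjusted over the list alone, median 1.55, camera adjusted p = 6.2e-18, adjusted p = 0.0378 with an estimated correlation). Of 29 Treg identity genes 18 rose and 0 fell (21 and 0 adjusted over the list alone, median 0.53, adjusted p = 1.6e-09, adjusted p = 0.1 with an estimated correlation). Co-inhibitory receptor genes rose in 9 of 11 cases (median 1.13, adjusted p = 2.8e-07, adjusted p = 0.0435 with an estimated correlation). Pdcd1 rose from 11.4 ± 0.351 to 49.8 ± 6.16. Of 30 trafficking receptor genes 18 rose and 4 fell (median 0.58, adjusted p = 3.0e-04, adjusted p = 0.0378 with an estimated correlation). Ccr4 rose from 2.69 ± 0.476 to 14.7 ± 2.25. Helper-lineage genes rose in 16 of 23 cases and fell in 0 (median 0.75, adjusted p = 1.6e-09, adjusted p = 0.0701 with an estimated correlation). Il21, a follicular helper cytokine, rose from 0.125 ± 0.0610 to 2.89 ± 1.1.

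Of 24 resting T cell genes 11 fell and 0 rose between the KO fractions (14 and 1 adjusted over the list alone, median log2 -0.39, limma camera, Benjamini-Hochberg adjusted p = 2.5e-12, adjusted p = 0.0378 with an estimated correlation). Dapl1 fell from 56.2 ± 9.66 to 19.6 ± 6.64 (log2 -1.51, SE 0.21) and Igfbp4 from 211 ± 28.9 to 79.0 ± 36.6 (log2 -1.49, SE 0.31). Klf2 fell from 163 ± 9.97 to 80.7 ± 11.9 (log2 -1.01, SE 0.10). Interferon-stimulated genes fell in 14 of 28 cases and rose in 1 (median -0.25, adjusted p = 3.2e-09, adjusted p = 0.1 with an estimated correlation). Ifit3, an antiviral protein, fell from 29.4 ± 3.06 to 17.5 ± 1.59. Immediate early and stress genes rose in 8 of 25 cases and fell in 1 (adjusted p = 0.0175, adjusted p = 0.293 with an estimated correlation). That p was 0.0573 without KO CD62Lhi replicate 3 and 0.0571 without KO CD62Llo replicate 1 (range over the alternatives 0.00186 to 0.293). Egr2, a factor induced by antigen receptor signals, rose from 11 ± 0.335 to 24.6 ± 5.24. Ribosomal protein genes fell in 45 of 82 cases (median -0.24, adjusted p = 9.2e-27, adjusted p = 0.1 with an estimated correlation), but in 2 after quantile normalization (median -0.05, adjusted p = 0.0923) and in 63 after median centring (median -0.32, range of adjusted p over the alternatives 2.1e-33 to 0.1). Ezh2 rose by 0.43 (SE 0.11, adjusted p = 0.0282). This call was lost without KO CD62Lhi replicate 1 (adjusted p = 0.098) or replicate 3 (0.054), or without KO CD62Llo replicate 2 (0.0935) or replicate 3 (0.0571), with a range over the alternatives of 0.0152 to 1.

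Smaller counts in KO CD62Llo came from 3 rises among 11 PRC2 genes (limma camera, Benjamini-Hochberg adjusted p = 0.0612), 4 among 18 PRC1 genes (0.923) and 1 among 33 cell cycle genes (0.405). There were 7 rises among 19 glycolysis genes (0.186) and 8 rises and 2 falls among 24 apoptosis and p53 genes (0.242). TGF-beta and Smad genes had 5 rises and 1 fall (0.92) and classical Polycomb targets 2 falls (0.223). Cholesterol synthesis genes (0.971) and histone genes (0.223) had 0 calls. Cbx6 rose from 13.1 ± 0.679 to 23.7 ± 1.13 and Mcm6 from 34.6 ± 1.67 to 49.5 ± 4.85.

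Between the KO fractions limma with Benjamini-Hochberg called 1852 genes, 1365 higher and 487 lower in CD62Llo, of which 257 and 40 had an absolute log2 change of at least 1. Quantile normalization gave 954 higher and 797 lower, and median centring 1007 higher and 987 lower. The 2 groups did not overlap for 3974 genes (34.8%, against 10% by chance). Leaving out KO CD62Lhi replicate 1 or 2 or KO CD62Llo replicate 2 lowered the calls to 1207, 1218 and 1187.

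The HET and KO fraction changes, which share no library, had a Spearman rho of 0.771 and a Pearson r of 0.508 over the 11431 genes. Of the calls, 1223 genes such as Tigit and Lag3 were higher in CD62Llo in both genotypes, where independent lists would share 256. Another 443 such as Dapl1 and Klf2 were lower in both (43.2 for independent lists), and 1 was called in opposite directions. Among the 1365 genes higher in KO CD62Llo the median log2 change was 0.68 in HET and 0.52 in KO, and 78.1% had the larger change in HET. Among the 487 lower genes the medians were -0.56 and -0.38, and 84.6% changed more in HET.

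**Figure D2:**
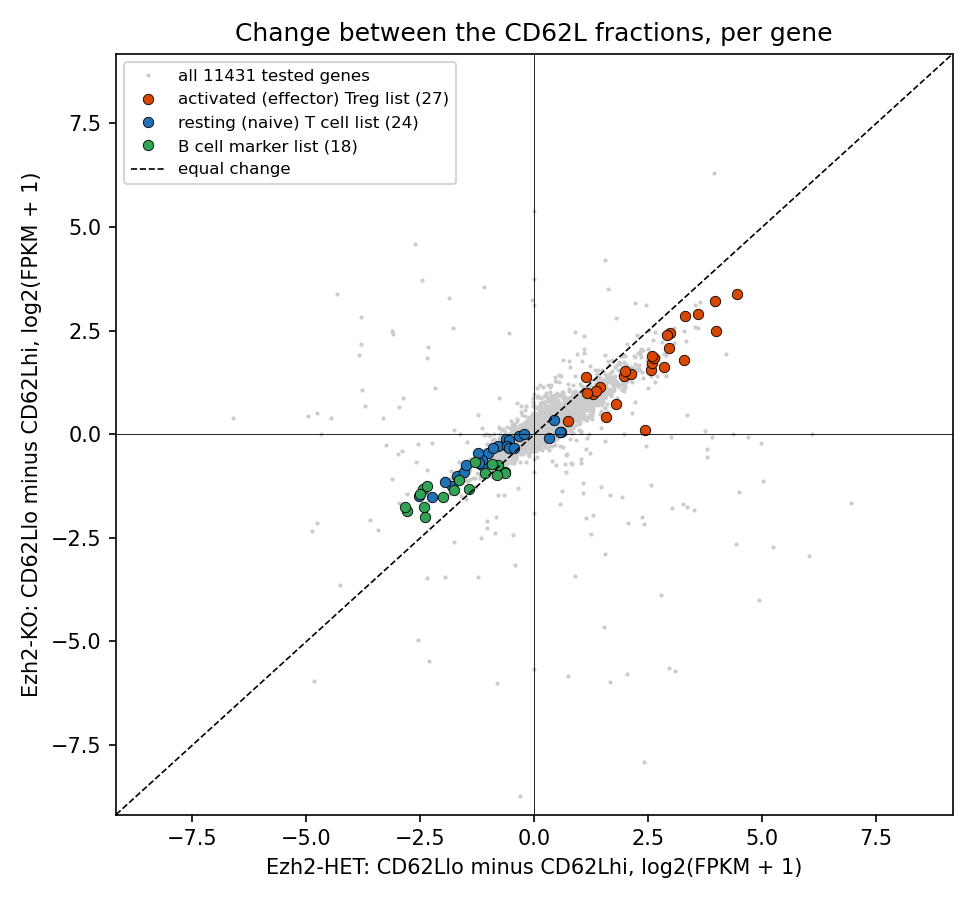
Log2 change of FPKM + 1 from CD62Lhi to CD62Llo in HET cells (x) and KO cells (y), with each of 11431 genes as a grey point, 27 activated Treg genes in orange, 24 resting T cell genes in blue, 18 B cell genes in green and a dashed line of equal change. The activated genes had a median of 2.56 in HET and 1.55 in KO, and the resting genes -0.96 and -0.39.

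In the CD62Lhi fraction 0 genes passed between KO and HET in the fit of all 11 libraries (limma, Benjamini-Hochberg). A fit of the CD62Lhi libraries alone called 5, 4 higher and 1 lower in KO. S100a4 (chromosome 3, 90603770 to 90606045) averaged 22.2 ± 7.07 (n = 2) in HET and 6.72 ± 1.70 (n = 3) in KO (log2 -1.58, SE 0.23, adjusted p = 0.771). Its neighbour S100a6, another calcium-binding protein gene, averaged 16 ± 1.74 and 6.05 ± 2.32 (log2 -1.32, SE 0.28, adjusted p = 1). Cxcr3 averaged 4.86 ± 1.71 and 2.28 ± 0.386, Ccr4 4.57 ± 0.83 and 2.69 ± 0.476, and Dapl1 34.8 ± 1.18 and 56.2 ± 9.66. At an unadjusted p of 0.05 there were 328 genes, where 572 would be called by chance, and the groups did not overlap for 22.2% of genes against 20% by chance. Leaving out HET CD62Lhi replicate 2 gave 5 calls, HET CD62Llo replicate 3 gave 3, and HET CD62Lhi replicate 1, HET CD62Llo replicate 2, KO CD62Lhi replicate 1 or KO CD62Llo replicate 2 gave 1 each.

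Gene lists in CD62Lhi moved by small amounts with no member called over all genes, and adjusted over the list alone 2 activated Treg genes fell. By limma camera with Benjamini-Hochberg the activated Treg list had a median log2 change of -0.20 (adjusted p = 1.9e-05, adjusted p = 0.314 with an estimated correlation). Treg identity had -0.14 (adjusted p = 5.9e-04, adjusted p = 0.365 with an estimated correlation, 0.0778 without KO CD62Lhi replicate 2, range over the alternatives 5.1e-10 to 0.365). Resting T cell genes had 0.05 (adjusted p = 0.0381, adjusted p = 0.365 with an estimated correlation, 0.188 without HET CD62Lhi replicate 1 and 0.21 without KO CD62Lhi replicate 2, range 0.007 to 0.76). Tnfrsf4, a co-stimulatory receptor of Tregs, averaged 142 ± 8.74 in HET and 115 ± 5.77 in KO. Cholesterol synthesis genes had a median of -0.22, with 2 of 20 positive (adjusted p = 4.0e-09, adjusted p = 0.314 with an estimated correlation). Fdft1, which makes squalene, averaged 10.7 ± 0.609 and 8.36 ± 0.840 and Cyp51, a sterol demethylase, 8.38 ± 0.200 and 5.97 ± 0.868. Interferon-stimulated genes had a median of 0.12, with 23 of 28 positive (adjusted p = 8.0e-07, adjusted p = 0.314 with an estimated correlation, 0.0795 without HET CD62Lhi replicate 1, range 8.7e-11 to 0.314). Ifit3 averaged 22.7 ± 2.96 and 29.4 ± 3.06. Immediate early and stress genes had -0.16 (adjusted p = 6.0e-05, adjusted p = 0.314 with an estimated correlation). Dnajb1, a heat shock co-chaperone, averaged 46.5 ± 6.13 and 36.8 ± 5.24. Ribosomal protein genes had -0.09 (adjusted p = 1.6e-09, adjusted p = 0.382 with an estimated correlation), a result lost under quantile normalization (adjusted p = 0.462) and kept under median centring (3.0e-10, range 3.5e-15 to 0.462).

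The other lists did not pass in CD62Lhi by limma camera with Benjamini-Hochberg. Adjusted p was 0.964 for PRC2, 0.0776 for PRC1, 0.605 for classical Polycomb targets, 0.0968 for helper-lineage genes, 0.379 for co-inhibitory receptors and 0.0776 for trafficking receptors. It was 0.929 for cell cycle, 0.0776 for apoptosis and p53, 0.0696 for glycolysis, 0.605 for TGF-beta and Smad and 0.567 for histone genes. Cbx8, a PRC1 chromodomain gene, averaged 9.79 ± 1.14 in HET and 7.54 ± 0.221 in KO, and Suz12, a PRC2 core gene, 21.0 ± 0.00643 and 22.5 ± 2.38.

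In the CD62Llo fraction KO cells had lower levels of activated Treg genes and higher levels of resting T cell genes than HET cells. S100a4 fell from 223 ± 24.8 (n = 3) to 54.9 ± 10.6 (n = 3), a log2 change of -2.01 (SE 0.21, limma, Benjamini-Hochberg adjusted p = 0.00237), and S100a6 from 101 ± 8.16 to 24.8 ± 7.19 (log2 -2.03, SE 0.25, adjusted p = 0.0041). Klrg1 (chromosome 6, 122270597 to 122282833), a receptor of terminally differentiated cells, fell from 6.27 ± 4.12 to 0.338 ± 0.424 (log2 -2.34, SE 0.35, adjusted p = 0.00854). Ccr2 (chromosome 9, 124102183 to 124109140) fell from 30.7 ± 10.5 to 7.18 ± 3.26 (log2 -1.97, SE 0.30), and Icos, a co-stimulatory receptor, from 116 ± 20.7 to 52.6 ± 7.51 (log2 -1.12, SE 0.17). Tigit fell from 128 ± 41.8 to 36.3 ± 10.3 (log2 -1.78, SE 0.31, adjusted p = 0.0151). Its adjusted p was 0.0555 without HET CD62Llo replicate 2 and 0.0595 without KO CD62Llo replicate 1 (range over the alternatives 0.00617 to 1). Il1r2 fell from 38.0 ± 9.44 to 13.4 ± 1.75, and Myo1f, a myosin of migrating leukocytes, from 20.2 ± 0.688 to 6.12 ± 1.75. Lilrb4, an inhibitory receptor gene, and Gp49a, whose sequence is near identical to it, fell from 10.6 ± 2.07 to 2.76 ± 0.596 and from 7.09 ± 1.46 to 1.95 ± 0.660.

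Of 27 activated Treg genes 18 fell and 0 rose in KO CD62Llo (24 and 0 adjusted over the list alone), and 0 had a positive log2 change. The median was -0.89 (limma camera, Benjamini-Hochberg adjusted p = 6.8e-20, adjusted p = 0.0412 with an estimated correlation). Treg identity genes fell in 7 of 29 cases (14 adjusted over the list alone, median -0.36, adjusted p = 1.0e-06, adjusted p = 0.186 with an estimated correlation). Ctla4 averaged 217 ± 47.0 and 142 ± 12.9 (log2 -0.59, SE 0.15, adjusted p = 0.065, but 0.0117 with the replicate number as a block, range 0.0117 to 1). Cd44 averaged 33.2 ± 2.11 and 24.6 ± 4.94 (adjusted p = 0.0794).

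Of 24 resting T cell genes 13 rose and 0 fell in KO CD62Llo (17 and 0 adjusted over the list alone). The median log2 change was 0.56 (limma camera, Benjamini-Hochberg adjusted p = 7.1e-17, adjusted p = 0.0178 with an estimated correlation). Satb1 (chromosome 17, 51736187 to 51833290), a chromatin organizer of naive T cells, rose from 23.9 ± 1.67 to 43.7 ± 3.19 (log2 0.84, SE 0.07, adjusted p = 0.00172), and Dapl1 from 6.63 ± 0.658 to 19.6 ± 6.64 (log2 1.38, SE 0.21). Bcl2 rose from 36.5 ± 0.990 to 57.2 ± 7.42 (log2 0.63). Igfbp4 rose from 26.1 ± 8.51 to 79.0 ± 36.6 (log2 1.51, SE 0.31, adjusted p = 0.0271). Its adjusted p was 0.0606 without HET CD62Llo replicate 1, 0.084 without HET CD62Llo replicate 2, 0.0814 without KO CD62Llo replicate 1 and 0.0537 without KO CD62Llo replicate 3 (range over the alternatives 0.00874 to 1). Outside the list, Rnf130 (chromosome 11, 50025331 to 50104733), a ubiquitin ligase gene, rose from 9.35 ± 0.175 to 19.7 ± 1.39 (log2 1, SE 0.07, adjusted p = 6.4e-04). St8sia6, a sialyltransferase gene, rose from 12.3 ± 0.571 to 22.0 ± 3.04, and Treml2, a surface receptor gene, from 17.9 ± 2.52 to 32.4 ± 5.95.

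Helper-lineage genes fell in 8 of 23 cases in KO CD62Llo and rose in 0 (15 and 0 adjusted over the list alone, median log2 -0.52, limma camera, Benjamini-Hochberg adjusted p = 2.7e-08, adjusted p = 0.117 with an estimated correlation). Il18rap (chromosome 1, 40515362 to 40549297), an IL-18 receptor chain, fell from 5.67 ± 0.616 to 1.66 ± 0.182 (log2 -1.32, SE 0.10, adjusted p = 6.4e-04). Il4, the Th2 cytokine, fell from 4.17 ± 1.30 to 0.819 ± 0.234 (log2 -1.48) and Cxcr3 from 44.9 ± 7.96 to 17.2 ± 4.61 (log2 -1.35). Ifng averaged 3.79 ± 0.294 and 2.28 ± 0.743 (adjusted p = 0.0784). Trafficking receptor genes fell in 12 of 30 cases and rose in 2 (15 and 4 adjusted over the list alone, median -0.40, adjusted p = 0.00205, adjusted p = 0.0582 with an estimated correlation). Ccr4 fell from 42.8 ± 9.55 to 14.7 ± 2.25 and Cxcr6, a receptor of tissue-resident cells, from 16.6 ± 5.23 to 5.54 ± 0.160. Co-inhibitory receptor genes fell in 2 of 11 cases (6 adjusted over the list alone, median -0.27, adjusted p = 4.0e-04, adjusted p = 0.156 with an estimated correlation). Glycolysis genes fell in 3 of 19 cases (11 fell and 1 rose adjusted over the list alone, median -0.17, adjusted p = 7.1e-04, adjusted p = 0.33 with an estimated correlation). Aldoc, an aldolase gene, fell from 3.28 ± 0.560 to 1.04 ± 0.270. Interferon-stimulated genes rose in 2 of 28 cases (median 0.11, adjusted p = 8.1e-05, adjusted p = 0.283 with an estimated correlation). Usp18 rose from 20.9 ± 2.15 to 32.5 ± 4.23.

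Among Polycomb genes in KO CD62Llo, Pcgf2 fell from 2.86 ± 0.377 to 0.886 ± 0.0528 (log2 -1.03, SE 0.10, limma, Benjamini-Hochberg adjusted p = 0.00206) and Aebp2 from 98.6 ± 6.35 to 72.9 ± 2.49 (log2 -0.43, SE 0.06, adjusted p = 0.00811). PRC2 as a list gave 1 fall of 11 (camera adjusted p = 0.0771) and PRC1 2 falls of 18 (adjusted p = 0.128). Of the 5 testable classical Polycomb targets 0 passed (adjusted p = 0.117). Cdkn1c, a cell cycle inhibitor, averaged 0.648 ± 0.234 in HET and 0.959 ± 0.119 in KO, and Hoxb4, a homeobox factor, 0.703 ± 0.485 and 1.08 ± 0.312.

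Apoptosis and p53 genes rose in 1 and fell in 3 of 24 cases in KO CD62Llo (limma camera, Benjamini-Hochberg adjusted p = 0.0463, adjusted p = 0.237 with an estimated correlation). Gadd45b fell from 28.2 ± 2.15 to 17.4 ± 1.41. That list was lost without HET CD62Llo replicate 2 (0.0854) or 3 (0.124) and without KO CD62Llo replicate 1 (0.0684) or 2 (0.102), and with the replicate number as a block (0.065), with a range over the alternatives of 0.0181 to 0.237. Ribosomal protein genes had 0 calls with 74 of 82 positive (median log2 0.10, adjusted p = 1.5e-10, adjusted p = 0.33 with an estimated correlation). Their shift was lost under quantile normalization (median -0.00457, adjusted p = 0.628), while median centring gave 0.14 with 3 rises (range over the alternatives 3.3e-17 to 0.628). Histone genes had 0 calls (median 0.21, adjusted p = 3.1e-05, adjusted p = 0.368 with an estimated correlation, 0.0507 without KO CD62Llo replicate 1, range 9.3e-09 to 0.368). Of 16 TGF-beta and Smad genes 2 rose and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 0.052, 0.0458 with the block, range 0.0254 to 0.777), and Smad7 averaged 15.6 ± 1.46 in HET and 22.2 ± 2.08 in KO. Cell cycle genes (adjusted p = 0.76), immediate early and stress genes (0.0819) and cholesterol synthesis genes (0.207) had 0 calls. Mcm6 averaged 62.6 ± 5.64 and 49.5 ± 4.85 (adjusted p = 0.0608, but 0.0148 with the block).

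Between KO and HET CD62Llo cells limma with Benjamini-Hochberg called 526 genes, 155 higher and 371 lower in KO, of which 7 and 36 had an absolute log2 change of at least 1. Quantile normalization gave 237 higher and 310 lower, and median centring 226 higher and 281 lower. The 2 groups did not overlap for 2312 genes (20.2%, against 10% by chance). Leaving out HET CD62Llo replicate 2 or 3 lowered the calls to 182 or 303, and leaving out KO CD62Llo replicate 1 or 3 lowered them to 184 or 284. KO CD62Llo replicate 3 stood at 0.135 on the first principal component (30.9% of the variance), against 13.6 and 24.8 for replicates 1 and 2, 28.4 to 33.4 for HET CD62Llo and -29.0 to -21.1 for the CD62Lhi libraries. A fit of the 6 CD62Llo libraries alone called 109 genes, 105 of them among the 526, with S100a4, Satb1 and Il18rap kept and Klrg1, Ccr2 and Dapl1 not called. The KO minus HET changes of the 2 fractions, which share no library, had a Spearman rho of 0.197 and a Pearson r of 0.0411.

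Of the 526 genes, 521 such as Tigit and Satb1 moved toward the HET CD62Lhi level by sign and 5 moved away from it. Genes that went past that level, such as Aldoc, count among the 521. S100a4 also counts among them, but it averaged lower in KO in the CD62Lhi fraction as well, without a call there. The HET CD62Llo libraries enter both the comparison of KO with HET CD62Llo and the one between the HET fractions. Among the top 526 genes 99.0% moved toward HET CD62Lhi. Data simulated with KO CD62Llo set to the HET CD62Llo means gave a median of 64.1% and a highest share of 69.0%. The simulation kept the other fitted group means and shared these libraries. It drew the noise of each gene independently, so noise common to many genes of a library is not covered. The overlap was 360 genes lower in KO and higher in HET CD62Llo than CD62Lhi (69.7 for independent lists) and 136 the other way (13.8 for independent lists). The covariance of the 2 sets of changes was -0.123 against -0.0397 simulated, a difference of -0.0832. With 3 HET CD62Llo libraries the shared controls could not be parted into 2 sets of 2, so part of the excess may come from the shared controls. Positions were taken on a scale with HET CD62Llo at 0 and HET CD62Lhi at 1, over list members called between the HET fractions with a mean FPKM of at least 5 in the higher group. These were 25 of 27 activated Treg, 19 of 24 resting T cell, 20 of 29 Treg identity and 9 of 18 B cell genes. The KO CD62Llo libraries had a mean position of 0.624 ± 0.0272 (n = 3) for activated Treg genes and 0.427 ± 0.104 for resting T cell genes. Their mean position was 0.539 ± 0.0501 for Treg identity genes and 0.197 ± 0.188 for B cell genes, the latter 0.0891 without KO CD62Llo replicate 3. Over all 287 genes called higher in HET CD62Llo with such a mean FPKM and an absolute log2 change of at least 1, the mean position was 0.467 ± 0.108 (0.499, 0.346 and 0.555 per library), and over the 82 lower genes 0.314 ± 0.128 (0.298, 0.195 and 0.450). Interferon-stimulated and ribosomal protein genes had mean positions of 0.345 ± 0.0160 and 0.212 ± 0.0716.

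The interaction, which asks whether KO minus HET differs between the fractions, passed for 1 of 11431 genes (limma, Benjamini-Hochberg), Mir1905, a microRNA gene of 82 bp inside Mex3a (chromosome 3, 88536301 to 88536382). Its FPKM were 60.9 and 152 in HET CD62Lhi, listed as 0 in each of the 3 HET CD62Llo libraries, 195, 120 and 128 in KO CD62Lhi and 230, 209 and 143 in KO CD62Llo. Il18rap had an interaction log2 of -1.12 (SE 0.14, adjusted p = 0.0771) and Satb1 0.75 (SE 0.11, adjusted p = 0.114). Rora, a lineage factor of tissue Tregs, had -1.05 (SE 0.16, adjusted p = 0.128) and Klrg1 -2.32 (SE 0.53, adjusted p = 0.244). As lists by camera, activated Treg genes had a median of -0.69 (adjusted p = 2.8e-14, adjusted p = 0.101 with an estimated correlation) and resting T cell genes 0.52 (adjusted p = 3.8e-14, adjusted p = 0.0312 with an estimated correlation). Adjusted p was 0.0827 for PRC2, 0.642 for PRC1, 0.332 for classical Polycomb targets, 0.773 for cell cycle and 0.448 each for interferon-stimulated, immediate early and apoptosis genes. It was 0.908 for plasma cell genes, 0.101 for CD8 T and NK cell genes and 0.388 for red cell and platelet genes, and the lists that passed are given with their values in the closing section. At an unadjusted p of 0.05 there were 868 genes.

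**Figure D3:**
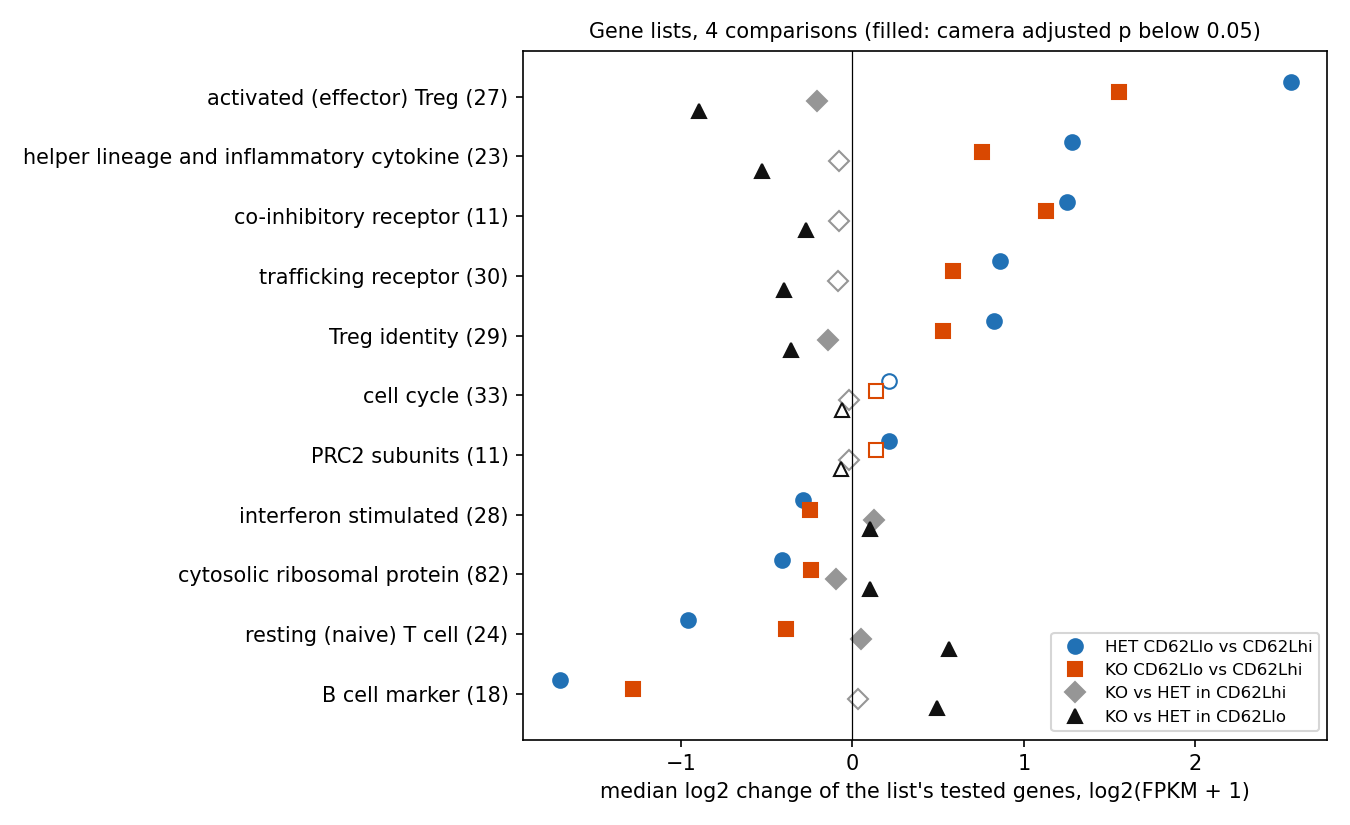
Median log2 change of FPKM + 1 of 11 gene lists (markers) in the 4 comparisons of 2 groups, filled where limma camera gave a Benjamini-Hochberg adjusted p below 0.05. Activated Treg genes stood at 2.56 and 1.55 between the fractions and -0.20 and -0.89 between the genotypes. Ribosomal protein genes stood at -0.41, -0.24, -0.09 and 0.10, and their shift in KO against HET CD62Llo was lost under quantile normalization.

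Of 18 B cell genes tested 15 fell and 0 rose in HET CD62Llo (16 and 0 adjusted over the list alone, median log2 -1.71, limma camera, Benjamini-Hochberg adjusted p = 5.0e-12, adjusted p = 0.189 with an estimated correlation). In KO CD62Llo 15 fell (17 adjusted over the list alone, median -1.28, adjusted p = 4.5e-14, adjusted p = 0.141 with an estimated correlation). Cd79a, a chain of the B cell receptor, averaged 28.1 ± 2.64, 3.33 ± 1.24, 30.1 ± 9.69 and 8.80 ± 7.21 in HET CD62Lhi, HET CD62Llo, KO CD62Lhi and KO CD62Llo. Ly6d, a B lineage antigen, averaged 17.8 ± 1.97, 1.65 ± 0.379, 16.4 ± 4.78 and 4.41 ± 2.53. KO minus HET gave a B cell list median of 0.50 in CD62Llo with 0 calls (adjusted p = 1.9e-05, adjusted p = 0.34 with an estimated correlation, 0.0704 without KO CD62Llo replicate 3, range over the alternatives 5.6e-08 to 0.34) and adjusted p = 0.327 in CD62Lhi.

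CD8 T and NK cell genes fell in 5 of 7 cases and rose in 2 in HET CD62Llo (limma camera, Benjamini-Hochberg adjusted p = 0.01, adjusted p = 0.189 with an estimated correlation) and likewise in KO CD62Llo (adjusted p = 0.0054, adjusted p = 0.149 with an estimated correlation). Cd8b1, a co-receptor chain of cytotoxic T cells, averaged 31.4 ± 2.18, 10.7 ± 1.79, 26.0 ± 2.85 and 11.4 ± 2.47 in the same group order. Prf1, a pore-forming protein, averaged 5.1 ± 1.73, 1 ± 0.345, 5.45 ± 0.865 and 1.99 ± 0.213. KO minus HET gave adjusted p = 0.0968 in CD62Lhi and 0.55 in CD62Llo. Of 14 myeloid genes 2 rose in HET CD62Llo (adjusted p = 0.503) and 2 in KO CD62Llo (adjusted p = 0.0172, adjusted p = 0.693 with an estimated correlation, 0.0571 without KO CD62Llo replicate 1 and 0.0818 without replicate 2, range over the alternatives 1.7e-10 to 0.693). Lyz2, a lysozyme near identical to Lyz1, had FPKM of 124, 219 and 25.6 in the KO CD62Llo libraries. KO minus HET for myeloid genes gave adjusted p = 0.781 in CD62Lhi and a median of 0.51 in CD62Llo with adjusted p = 0.0347 (adjusted p = 0.638 with an estimated correlation). The latter list was lost, with adjusted p of 0.118, 0.145, 0.104 and 0.603, without HET CD62Llo replicate 2 or 3 or KO CD62Llo replicate 1 or 2 (range 3.4e-06 to 0.638).

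Plasma cell genes rose in 2 and fell in 1 of 4 cases in HET CD62Llo (limma camera, Benjamini-Hochberg adjusted p = 0.676) and rose in 1 in KO CD62Llo (adjusted p = 0.661). Derl3, of the secretory pathway, rose from 0.363 ± 0.0729 to 1.26 ± 0.329 in KO. There were 0 plasma cell calls between the genotypes (adjusted p = 0.77 in CD62Lhi and 0.84 in CD62Llo). Red cell and platelet genes had 0 calls of 6 in each comparison (adjusted p = 0.177, 0.353, 0.379 and 0.76 for HET fractions, KO fractions, CD62Lhi and CD62Llo). Hba-a1, a globin gene with near-identical copies, averaged 102 ± 8.18, 75.2 ± 64.6, 88.5 ± 119 and 59.6 ± 53.9. Of the stromal and endothelial list 2 genes could be tested, too few for a list test. Igfbp7, a matrix protein, rose from 0.228 ± 0.244 to 2.85 ± 0.330 in HET and from 0.261 ± 0.178 to 2.55 ± 0.667 in KO. Pecam1, an adhesion molecule also on naive T cells, fell from 69.6 ± 3.5 to 38.8 ± 1.79 and from 73.0 ± 5.23 to 52.6 ± 2.69. It was higher in KO than HET CD62Llo (log2 0.43, SE 0.07, adjusted p = 0.00878). Of the mitochondrially encoded list 0 genes were in the files. Of 115 list tests 57 passed with the preset correlation and 8 with an estimated correlation. The 8 were resting T cell genes in each comparison but KO against HET CD62Lhi, activated Treg genes between KO fractions and in CD62Llo, and co-inhibitory and trafficking receptors between KO fractions.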

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

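Of the tests below, those on CD62Lhi cells in the KO CD62Llo sort, on replicate 3 and on shared HET libraries were chosen only after the result was seen. The test on shared HET libraries replaced a simulation whose outcome had been seen, because a simulated bound excludes nothing, and the simulated values are given in the results.

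Results stood out here because KO minus HET differed between the fractions in the interaction test. Mir1905 had an interaction log2 of 7.001 (SE 0.47, limma, Benjamini-Hochberg adjusted p = 9.1e-04), with FPKM of 0 in the 3 HET CD62Llo libraries, so its size rests on the added 1 and bounds nothing. Its lower interval bound was 0 in 10 of the 11 libraries. Among lists, by limma camera, activated Treg genes had a median of -0.69 (adjusted p = 2.8e-14, adjusted p = 0.101 with an estimated correlation), resting T cell genes 0.52 (adjusted p = 3.8e-14, adjusted p = 0.0312 with an estimated correlation), Treg identity genes -0.24 (adjusted p = 0.00316, adjusted p = 0.496 with an estimated correlation) and helper-lineage genes -0.42 (adjusted p = 2.0e-07, adjusted p = 0.15 with an estimated correlation). Co-inhibitory receptor genes had -0.24 (adjusted p = 0.00295, adjusted p = 0.179 with an estimated correlation) and trafficking receptor genes -0.30 (adjusted p = 0.012, adjusted p = 0.119 with an estimated correlation). Treg identity was lost without HET CD62Llo replicate 3 (0.0769) or KO CD62Llo replicate 2 (0.0529), range over the alternatives 9.7e-05 to 0.496, and trafficking without KO CD62Llo replicate 2 (0.0996), range 0.00314 to 0.123.

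Ribosomal protein genes had a median interaction of 0.18 (limma camera, Benjamini-Hochberg adjusted p = 6.3e-21, adjusted p = 0.179 with an estimated correlation), which quantile normalization lowered to 0.01 (adjusted p = 0.875) and median centring kept at 0.20 (adjusted p = 1.3e-24), range over the alternatives 9.5e-28 to 0.875. Glycolysis genes had -0.12 (0.0296, adjusted p = 0.566 with an estimated correlation), lost without HET CD62Lhi replicate 1 (0.155), HET CD62Llo replicate 1 (0.162) or 2 (0.0769), KO CD62Lhi replicate 1 (0.0573) or KO CD62Llo replicate 1 (0.128), range 0.00254 to 0.954. Cholesterol synthesis genes had 0.10 (0.0132, adjusted p = 0.566 with an estimated correlation), lost without HET CD62Lhi replicate 2 (0.246), HET CD62Llo replicate 1 (0.288), KO CD62Lhi replicate 3 (0.0741) or KO CD62Llo replicate 3 (0.125) and with array weights (0.0685), range 3.4e-04 to 0.566. TGF-beta and Smad genes had 0.0558 (0.0291, adjusted p = 0.154 with an estimated correlation), lost without HET CD62Llo replicate 1 (0.14), KO CD62Lhi replicate 2 (0.0685) or KO CD62Llo replicate 3 (0.11), range 0.0116 to 0.859. Histone genes had 0.21 (0.00109, adjusted p = 0.566 with an estimated correlation), lost without KO CD62Llo replicate 1 (0.201), range 6.5e-06 to 0.566. B cell genes had 0.45 (0.00144, adjusted p = 0.566 with an estimated correlation), lost without KO CD62Llo replicate 3 (0.382), range 3.4e-08 to 0.566. Myeloid genes had 0.70 (0.0313, adjusted p = 0.673 with an estimated correlation), lost without HET CD62Lhi replicate 1 (0.609), HET CD62Llo replicate 2 (0.108) or 3 (0.135), KO CD62Lhi replicate 1 (0.0905) or KO CD62Llo replicate 1 (0.123) or 2 (0.418), and with quantile normalization (0.094), median centring (0.0852) or the replicate block (0.137), range 1.2e-06 to 0.673.

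Activated Treg genes in the KO CD62Llo libraries lay between the HET fractions, over the 25 of 27 called between these with a mean FPKM of at least 5, at positions of 0.643, 0.593 and 0.635. Replicate 3 as the whole cause is argued against by the lower position of the other 2, 0.593, where HET CD62Llo libraries reached 0.156. CD62Lhi cells in the CD62Llo sort would give activated and resting genes 1 position, and their difference was 0.243, 0.253 and 0.0937 in replicates 1 to 3 (0.166 reached by other libraries), while all 287 genes higher and all 82 lower in HET CD62Llo differed by 0.202, 0.151 and 0.105 (0.0804 reached by other libraries). In KO CD62Llo replicates 1 to 3 B cell genes stood at 0.0701, 0.108 and 0.412, and interferon-stimulated genes at 0.327, 0.35 and 0.357. Ribosomal protein genes stood at 0.154, 0.292 and 0.189. Each of these lay below the activated position of the same library. Treg identity genes, at 0.592, 0.533 and 0.493, and trafficking receptor genes, at 0.524, 0.402 and 0.576, also lay below it but nearer. Helper-lineage genes stood at 0.613, 0.558 and 0.691, above the activated position in replicate 3. Ribosomal protein genes stood at 0.753, 0.805 and 0.747 in KO CD62Lhi itself, so admixed KO CD62Lhi cells would not bring them to 1. The lists thus go against 1 shared position only in part. However, lists also spread within the KO CD62Lhi libraries, most widely from 0.747 to 1.45 in replicate 3. So CD62Lhi cells cannot be told apart from a change within the cells, such as one from Ezh2 loss, which was not tested. For activated genes the 3 shared HET CD62Llo libraries spread from -0.142 to 0.156, below the 0.593 to 0.643 of KO CD62Llo. The scale sets their mean of each gene at 0, and the genes were called with these libraries. So that spread cannot measure a chance shift common to all 3, and it may be technical. Chance values of these libraries stay open as a cause of the shift. In a fit of the 6 KO libraries alone, 82.1% of 1424 called genes changed more between the HET fractions (80.2% of 1524 after median centring). That share is measured against the same HET libraries, so it decides nothing here.

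Mir1905 is 82 bp long, and short genes may have unstable FPKM, since the 190 tested genes under 200 bp had a median residual SD of 2.27 against 0.105 for the others, a ratio of 21.6. Reads of its host Mex3a stay open as a cause. The host had an interaction log2 of 0.32 (SE 0.211, limma, Benjamini-Hochberg adjusted p = 0.758), but its FPKM of 0.471 to 2.14 in the 11 libraries lies near the floor, where log2(FPKM + 1) would hide a large change, so this test decides nothing. No biological explanation was tested for Mir1905.

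B cell genes moved together within the 6 CD62Llo libraries, with a median pairwise r of 0.729 against 0.0226 for the median and 0.294 for the highest of 100 random lists, so B cells that passed the sort on Foxp3-linked YFP may be a source of this signal. Cd79a had FPKM of 3.21, 2.15 and 4.63 in HET CD62Llo and 5.07, 4.23 and 17.1 in KO CD62Llo, and a second sort on Foxp3-linked YFP would remove B cells. Class II genes in the list, such as H2-Aa, are also made by other antigen-presenting cells, and 2 of the list's genes, Pax5 and Ebf1, are also in the Polycomb target list.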

How the results depend on the processing

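Of the tests below, the interval midpoint and the leave-one-out values of the correlation between contrasts were chosen only after the result was seen.

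Including HET CD62Lhi replicate 3, which is nearly empty and spread wide, left 355 calls between HET fractions, 64 between KO fractions, 1 and 3 for KO against HET in CD62Lhi and CD62Llo and 0 for the interaction. Among the HET fraction log2 changes it reversed were those of Ly6c1 to 0.56, Rnf2 -1.01, Tyms -0.40, Usp18 0.91, Pdk1 0.92, Fdps 1.33, Smad7 0.68, Rps19 3.11, Rpl34 0.91, Hist3h2a 0.60 and Cd8b1 0.19. The interaction no longer called the Treg identity, co-inhibitory, trafficking, cholesterol, TGF-beta and B cell lists, and the glycolysis list was reversed (adjusted p = 0.954, range over the alternatives 0.00254 to 0.954). The Spearman rho of the fraction changes fell to 0.249 and that of the genotype changes to 0.0704.

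A minimum absolute log2 change of 1 left 558, 297 and 43 calls between HET fractions, between KO fractions and between KO and HET CD62Llo. With the compared libraries alone KO against HET gave 5 calls in CD62Lhi, up from 0, and 109 in CD62Llo, down from 526. In that fit the spread is estimated from fewer libraries and is not shared with the other fraction. So the 0 calls in CD62Lhi depend on the spread shared by all groups in the main fit. The interaction had 4 calls without the filter and 7 with array weights, Mir1905 in each. Without the filter the rho of the fraction changes was 0.708. Under quantile normalization the shift of the ribosomal list in KO against HET CD62Llo was lost (adjusted p = 0.628, range 3.3e-17 to 0.628). Where no reason is given the cause was not tested.

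Leaving out each library in turn gave 1916 (HET CD62Lhi replicate 1) to 3337 calls between HET fractions, 1187 (KO CD62Llo replicate 2) to 1974 between KO fractions, 0 to 5 for KO against HET in CD62Lhi, 182 (HET CD62Llo replicate 2) to 610 in CD62Llo and 1 to 5 for the interaction, Mir1905 in each. Where 1 HET CD62Lhi library was left, the lone library was assumed to vary like the other groups. The rho was 0.708 to 0.785 for the fraction changes and 0.0812 to 0.279 for the genotype changes. The cell cycle list of KO against HET CD62Llo had adjusted p of 0.0367 to 0.982 and was called with the direction reversed at 0.0367, without HET CD62Llo replicate 1.

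With the replicate block there were 3636, 2287, 0, 755 and 1 calls in the order of contrasts above, 499 of the 755 among the 526, and rho of 0.800 and 0.268. For KO against HET CD62Llo the block added the TGF-beta and Smad list (0.0458) and, among named genes, Mcm6 (0.0148), Ebp (0.0489) and Ctla4 (0.0117), ended the apoptosis and p53 list (0.065) and changed no other call of a list or named gene. For the other contrasts same-numbered libraries correlated at r of 0.135 and 0.0732 between HET fractions, each best with its own number, 0.131, 0.0684 and 0.178 between KO fractions, where replicate 2 did not, and 0.0749 and -0.0325 in CD62Lhi, where replicate 2 did not. The variant on the authors' merged table was not run, as it has no replicates.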

Other observations

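Of the tests below, those on low genes and on changes apart from the fraction axis were chosen only after the result was seen, and for low genes a first split on HET CD62Llo values was dropped, since choosing genes low in a compared group fixes the direction.

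Among genes called between KO and HET CD62Llo (limma, Benjamini-Hochberg), 13 lay at least 1.2-fold outside the range of the HET groups, with a highest group mean of at least 3, 10 higher and 3 lower. Pik3r3, a regulatory subunit of phosphoinositide 3-kinase, rose from 1.59 ± 0.144 (n = 3) to 3.15 ± 0.506 (n = 3), a log2 change of 0.67 (SE 0.11, adjusted p = 0.0109). Slc22a17, an iron-linked receptor, rose from 2.64 ± 0.210 to 4.29 ± 0.264 (log2 0.54, SE 0.08) and Gng12, a G protein subunit, from 2.67 ± 0.110 to 4.31 ± 0.249 (log2 0.53, SE 0.08). Scmh1, a Polycomb-associated protein, rose from 4.12 ± 0.488 to 6.48 ± 0.593 (log2 0.55, SE 0.11). HET CD62Lhi (n = 2) averaged 1.26 ± 0.249 for Pik3r3, 1.57 ± 0.186 for Slc22a17, 3.05 ± 0.306 for Gng12 and 5.34 ± 0.480 for Scmh1. The cut against HET CD62Lhi was made on group means, with no test and no count expected by chance. Aldoc averaged 0.811 ± 0.162 in KO CD62Lhi and 1.04 ± 0.270 in KO CD62Llo, below both HET groups. The other genes above the range were Mir1905, Pde3b, Pik3cb, Prpf40b, Baz2b and Cep97, and Mgat4b and Tnfaip1 lay below it.

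Macrophage genes varied within both CD62Llo groups. Apoe, a lipid carrier, had FPKM of 131, 66.1 and 38.2 in the HET libraries and 194, 352 and 43.9 in the KO libraries. C1qb, a complement component, had 33.7, 9.74 and 8.02 in HET and 26.8, 51.5 and 5.75 in KO, and Lyz2 75.2, 50.8 and 40.1 in HET and 124, 219 and 25.6 in KO. In CD62Lhi Apoe had 47.6 and 21.6 in HET and 22.0, 32.1 and 27.8 in KO. C1qb had 15.9 and 3.67 in HET CD62Lhi and 4.91, 7.95 and 3.68 in KO CD62Lhi. Lyz2 was lower in CD62Lhi, at 12.9 and 8.87 in HET and 7.60, 10.9 and 8.87 in KO. Whether this RNA affects the positions given above was not tested.

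Loss of a repressor could raise genes that are otherwise low. Of called genes with a mean FPKM under 2 over the 11 libraries 14.3% were higher in KO CD62Llo (11 of 77) against 32.1% of the others (Fisher exact p = 0.00112). Of the 77 only 6 had no call between the HET fractions, 4 higher and 2 lower, too few to decide, so such a rise cannot be told apart from movement along the fraction axis. Among 27 called genes with no call between the HET fractions, 16 were higher and 11 lower (exact binomial p = 0.442), which leaves a change apart from that axis open. A direct test would be Polycomb histone marks at these genes in CD62Llo cells.

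For KO CD62Llo against KO CD62Lhi 1 of the 10 splits of the 6 libraries, the real one, gave as many as 1852 calls, and the highest other gave 1. For KO against HET CD62Llo 1 of 10, the real one, gave as many as 526, and the highest other gave 2. Same-numbered libraries correlate here. The 3 other splits that part all 3 pairs gave 0, 0 and 2 calls, and the 6 that part 1 pair gave 0 to 2. With 10 splits a share under 0.05 cannot be reached.

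A hypothesis from these data is that KO cells may take on the activated program of CD62Llo Tregs less fully. CD62Lhi cells in the sort stay an open alternative. The difference between activated and resting positions was 0.243, 0.253 and 0.0937 in replicates 1 to 3 (0.166 reached by other libraries). Over all higher and lower genes it was 0.202, 0.151 and 0.105 (0.0804 reached by other libraries). Chance values of the shared HET CD62Llo libraries stay open as a cause of the shift. Single-cell values of Tigit and Satb1 within the CD62Llo gate would tell a mixture of 2 cell states from an intermediate one.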
